A study of Mus musculus with 22 samples.

How the data were processed

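The series holds poly(A) RNA-Seq of mouse cells and tissues, per the labels prepared from 0.5 M cells for cultured samples and sequenced for 50 cycles on a HiSeq 3000. There were 22 libraries, each the only library of its group. The deposited files hold, per the file headers, an expected count, a TPM and an FPKM for each gene, in the layout of RSEM gene output. Expected counts are estimated reads per gene with shared reads divided among genes, deposited without normalization. TPM were scaled by the authors to a constant sum per library, and FPKM by the authors to reads per kilobase of transcript and sequencing depth (FPKM not used here). Per the submitters' processing notes, CASAVA 1.8.2, STAR, RSEM and bedtools were used with the mm10 genome, and neither the order of these steps nor their settings are stated.

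Each file had 24911 genes, 20674 of them protein-coding, of which 511 were at 0 in every library. The other 4237, among them 92 spike-in sequences, were at 0 in all libraries and were left out. Of the expected counts above 0, 86.1% were whole numbers (within 1e-09), and the rest were rounded before count models were fitted. Length minus effective length was 49.0 in 4 libraries (LPS+IL4 B, splenic B, ConA and CH12) and 48.56 at the lowest in the other 18. The cause of this difference was not tested. Genes at 0 in those 4 libraries and present in all other 18 are given as uncertain. Genes raised or partly shifted with it were not searched for, so results that use those 4 libraries can hold such genes. Total expected counts ran from 30.8 to 147.9 M. At a TPM of 9 to 11 the median count was 446.0 in Tfh, where counting error alone gives a 95% interval of -9.1% to 9.7%, and 2660.0 in ConA (-3.8% to 3.9%). These intervals leave out any spread between animals.

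Groups came from the labels alone. Comparisons, gene lists, the rule for named genes and a set of alternatives were fixed before the data were examined, and what was chosen later is named as such. The 8 libraries of Tfh, non-Tfh, Tfr and CD4+ T cells, each unmarked and MUT, were fitted with population and mutant label as terms. The 6 activated B cultures were fitted with IL4 and LPS as terms, and 7 primary B libraries were compared with 9 CD4 T libraries. Fits used edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, quasi-likelihood F-tests, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05). The 41 gene lists cover lymphocyte, myeloid, erythroid, neural, skin and metabolic themes, and 6 of their genes were missing from the files. Lists were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01, and again with the correlation estimated from the data, adjusted over the lists of a comparison. Members were also adjusted over the list alone.

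Comparisons that rest on a single library were read by a rule of size in place of a test. A gene met the rule when its log2(TPM + 1) differed by at least 2 from every comparison library in the same direction, or by at least 3 for basophils and back skin, with a TPM of at least 10 on the higher side. List medians were set against 10000 random lists matched on expression. Random genes were drawn independently, so these percentiles leave out correlation within a list and any spread between samples. Named genes were members of the lists, and the 12 genes per direction with the largest change among those past the threshold, with a mean TPM of at least 10 on the higher side and no overlap between sides. Gene models without a name and immunoglobulin and T-cell receptor segments were counted and not named. Some genes are not reported here. Lists on intestine and milk genes and the tests in the closing section were added later, as stated there.

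Tests were checked on simulated data with 100 genes changed per fold size. For the mutant label 65% of 2-fold and 94% of 4-fold changes were recovered among 13064 genes, with 10 false calls, and for Tfh against non-Tfh 20% and 83%, with 7. The mutant label term fits a change common to all populations. Its shares therefore do not cover changes that run opposite in the Tfh pair, which the closing section describes. For IL4 in activated B cells 0% and 4% were recovered among 12515 genes, with 2 false calls, and for B against CD4 T cells 49% and 82% among 12437, with 6. The IL4 comparison is thus blind to most changes of these sizes.

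Alternatives were RLE size factors, no filter, DESeq2 1.42.0, limma on log2(TPM + 1), other covariates and library sets, TMM-scaled CPM, a pseudocount of 0.1 and a TPM minimum of 1 for size rules, and each library left out in turn. A population or stimulus left with a lone library was then assumed to vary like the others. Tables and figures were made with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Chromatin accessibility data of the study and sequence reads were not analysed here.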

Results

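The data are poly(A) RNA profiles of mouse primary cells, tissues and a lymphoma cell line, made beside chromatin accessibility data (not analysed here) for a resource on where transcription factors bind. There were 22 libraries in 22 groups of 1. Of these, 7 were primary B cells: splenic B cells and 6 activated cultures, labelled LPS, LPS+IL4, LPS+IL21, LPS+a-d-dextran, aCD40+IL4 and aBCD180 (LPS is lipopolysaccharide, a bacterial B-cell stimulus, and IL4 and IL21 are cytokines of helper T cells). A further 9 were CD4 T cells: follicular helper (Tfh), non-Tfh, follicular regulatory (Tfr) and CD4+ cells, each as an unmarked and a MUT library, and CD4+ cells activated with ConA, the T-cell mitogen concanavalin A. The others were CH12 (a B-lymphoma line, clone bc5), basophils, putamen, medulla oblongata, sensorimotor cortex and back skin. Total expected counts ran from 30.8 M in LPS B to 147.9 M in CD4+ ConA, with a median of 46.2 M. As no group had a second library, tests set populations or stimuli against the spread between related libraries. The labels do not say whether libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical. Log2 fold changes are given ± SE, and levels as TPM, mean ± SD over the n libraries of a side.

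Sex-linked transcripts separated the libraries. Ddx3y, a Y-linked RNA helicase gene, lay between 27.3 and 103.6 TPM in the LPS+IL21 B, splenic B, basophil, putamen, medulla, ConA and back skin libraries. It was at most 0.11 TPM in the other 15, which included the 8 unstimulated or sorted CD4 T libraries and the cortex. Splenic and most activated B cells, ConA and CD4+ T cells, and cortex and the other brain regions thus differed in this marker as well as in their labels.

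Tfh cells, the CD4 T cells that help B cells in follicles, were compared with activated CD4 T cells sorted as negative for CXCR5, PD1 and CD25 (n = 2 libraries per side). Genes of the Tfh programme were higher in Tfh cells. Bcl6, the transcription factor that directs the Tfh fate, was higher by a log2 fold change of 2.21 ± 0.16 (82.7 ± 3.06 against 16.5 ± 2.25 TPM, edgeR adjusted p = 0.00487). Il21, a cytokine that acts on germinal centre B cells, was higher by 5.77 ± 0.53 (edgeR adjusted p = 0.00769). Sostdc1, a secreted BMP antagonist, was higher by 8.96 ± 0.38 (138 ± 11.7 against 0.23 ± 0.04 TPM). Of the 22 programme genes, 14 rose, and 17 rose and 2 fell adjusted over the list alone (camera adjusted p = 2.79e-09, and adjusted p = 0.155 with an estimated correlation). Cxcr5 and Pdcd1, which encode sorting markers and so are no finding, were higher by 2.22 ± 0.29 and 4.14 ± 0.39. Regulatory T-cell genes also rose, 10 of 20 and 14 adjusted over the list alone (camera adjusted p = 2.91e-07, and adjusted p = 0.584 with an estimated correlation). This list holds Il2ra, which encodes the sorting marker CD25. The non-Tfh cells were sorted as CD25-negative, which can leave out regulatory cells, and the Tfh label states no such sort. The rise of regulatory genes cannot be told apart from that difference in sorting. Foxp3, the transcription factor of regulatory T cells, rose by 2.88 ± 0.48, with 143 TPM in Tfh and 69.2 in Tfh MUT against 13.5 ± 6.07 in non-Tfh. Il10, an inhibitory cytokine gene, rose by 3.37 ± 0.37. The naive T-cell genes went the other way: 13 of 16 fell, and 16 adjusted over the list alone (camera adjusted p = 5.8e-13, and adjusted p = 0.0622 with an estimated correlation). Satb1, a chromatin organiser, changed by -3.82 ± 0.27, and Il7r, the IL7 receptor, by -2.28 ± 0.25 (edgeR adjusted p = 0.0109). Among the 19 effector helper genes, Ccr2, a chemokine receptor of inflammatory cells (-1.37 ± 0.26), Runx3 and Il12rb2 fell. Eomes (2.53 ± 0.50), a T-box factor of cytotoxic cells, rose. Adjusted over the list alone 2 rose and 5 fell, and the list was not called (camera adjusted p = 0.066). The natural killer receptors Klrk1 (-3.75 ± 0.53) and Klrd1 (-3.06 ± 0.54) fell. Of 24 proliferation genes 3 rose, 6 adjusted over the list alone (camera adjusted p = 1.66e-06, and adjusted p = 0.814 with an estimated correlation), among them Mki67 (1.46 ± 0.30), a marker of dividing cells. Of 16 glycolysis genes the lactate exporter Slc16a3 (2.61 ± 0.35) and the enzyme Tpi1 (1.36 ± 0.21) rose, and 4 did adjusted over the list alone (camera adjusted p = 0.016, and adjusted p = 0.584 with an estimated correlation). Outside the lists, Cebpa, a myeloid transcription factor, rose by 5.94 ± 0.60 (101 ± 12 against 1.67 ± 1.42 TPM), Spp1 (osteopontin) by 8.14 ± 1.05 and Penk (proenkephalin) by 6.90 ± 1.46. Mmp9, a matrix protease, fell by 2.67 on the log2 scale.

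In this comparison edgeR called 860 of 13064 genes, 526 higher and 334 lower in Tfh cells (466 and 192 by at least 2-fold). DESeq2 called 2351 and limma 1075. Transcripts of B cells moved with the populations: the median TPM of 22 B identity genes was 18.1 in Tfh, 37.9 in Tfh MUT, 13.3 in non-Tfh and 15.8 in non-Tfh MUT. Cd22 alone of the 22 rose (2.64 ± 0.30), and the list was not called (camera adjusted p = 0.0783). Without the Tfh MUT and Tfr libraries, an alternative chosen after seeing the data, 3221 genes were called. The count fell to 0 without the non-Tfh library, to 0 without non-Tfh MUT and to 404 without either CD4+ library, and rose to 3561 without the Tfh library.

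**Figure D1:**
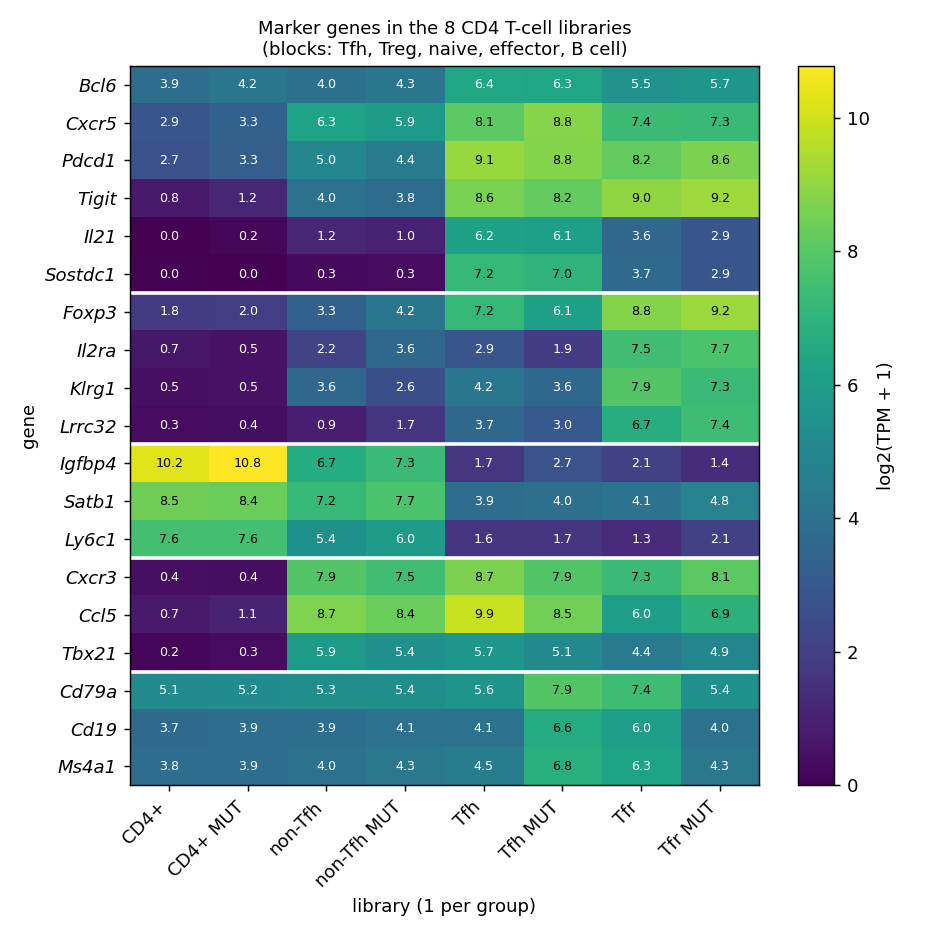
Levels of 19 marker genes (vertical axis) in the 8 CD4 T-cell libraries (horizontal axis, 1 library per group), coloured and printed as log2(TPM + 1), with blocks of Tfh, Treg, naive, effector and B-cell genes. Sostdc1 stands at 7.2 in Tfh and 7.0 in Tfh MUT against 0.3 in the non-Tfh libraries, and Cd79a at 7.9 in Tfh MUT and 7.4 in Tfr against 5.1 to 5.6 in the other 6.

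Tfr cells, follicular cells with regulatory function, were sorted as positive for CXCR5, PD1 and CD25, and were set first against Tfh cells (n = 2 libraries per side). Klrg1, an inhibitory receptor of terminally differentiated regulatory T cells, rose by 3.78 ± 0.31 (199 ± 54.5 against 14.4 ± 4.68 TPM, edgeR adjusted p = 0.0173), as did the regulatory T-cell receptor gene Gpr83 (2.23 ± 0.22). Those were 2 of 20 regulatory genes, and 16 rose adjusted over the list alone (camera adjusted p = 2.88e-15, and adjusted p = 0.317 with an estimated correlation), among them Il2ra, the sorting marker CD25, which is no finding. Foxp3 stood at 506 ± 103 against 106 ± 52.1 TPM, a log2 difference of 2.21 ± 0.47 that did not pass over all genes (edgeR adjusted p = 0.154). Tfh genes fell: Sostdc1 by 3.97 on the log2 scale, and Cd40lg (-1.73 ± 0.18), the ligand through which T cells license B cells. Slamf6 (-1.28 ± 0.15), an adhesion receptor of T and B cells, and Slc26a11 (-2.49 ± 0.28), a sulfate transporter, fell too. These were 4 of 22, and 13 adjusted over the list alone (camera adjusted p = 1.73e-10, and adjusted p = 0.26 with an estimated correlation). Bcl6 (-0.83 ± 0.16) did not pass over all genes (edgeR adjusted p = 0.123). Of 16 naive T-cell genes the transcription factors Tcf7 (-1.64 ± 0.14) and Klf2 (-1.63 ± 0.20) and the egress receptor S1pr1 (-1.59 ± 0.15) fell, 5 adjusted over the list alone (camera adjusted p = 0.0205, and adjusted p = 0.317 with an estimated correlation). Among effector helper genes Il1rl1, the IL33 receptor, rose by 3.79 ± 0.23 and Ccr6, a chemokine receptor, by 2.08 ± 0.21, and Gzmk, a granzyme gene outside the lists, changed by -4.36 ± 0.38 (4.96 ± 0.57 against 102 ± 23.1 TPM).

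Of 13064 genes edgeR called 52 between Tfr and Tfh cells, 14 higher and 38 lower (14 and 36 by at least 2-fold), DESeq2 called 632 and limma 109. For 3 further lists camera made a call while edgeR passed no member over all genes. The first was ribosome biogenesis (median log2 fold change 0.28, camera adjusted p = 0.000367, and adjusted p = 0.842 with an estimated correlation, 2 members under an unadjusted p of 0.05, 0 by DESeq2 and 0 by limma). The second was heat shock (0.29, camera adjusted p = 0.0192, and adjusted p = 0.317 with an estimated correlation, 2 unadjusted, 0 and 0). The last was CD8 and natural killer genes (-1.20, camera adjusted p = 0.00424, and adjusted p = 0.374 with an estimated correlation, 5 unadjusted, 4 and 0). The median TPM of B identity genes was 34.3 in Tfr and 15.0 in Tfr MUT. Without the Tfh MUT and Tfr libraries, chosen after seeing the data, 1033 genes were called. Every single leave-out moved the count by over 1.5 times: it was 458 without Tfh, 300 without Tfh MUT, 0 without non-Tfh or without non-Tfh MUT, 1 without Tfr, 0 without Tfr MUT, and 15 without either CD4+ library.

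Against non-Tfh cells, all 20 regulatory genes rose in Tfr cells, over all genes and adjusted over the list alone (camera adjusted p = 2.88e-13, and adjusted p = 0.526 with an estimated correlation). They include Il2ra, which encodes the sorting marker CD25, and the Tfh programme includes Cxcr5 and Pdcd1, so the rises of these 3 are no finding. Foxp3 rose by 5.08 ± 0.53 (506 ± 103 against 13.5 ± 6.07 TPM, edgeR adjusted p = 0.00407), Ctla4, an inhibitory receptor, by 3.20 ± 0.28, and Lrrc32, which displays latent TGF-beta, by 6.34 ± 0.56. The Tfh programme rose in 12 genes and fell in 4. It rose in 14 and fell in 5 adjusted over the list alone (camera adjusted p = 0.0208, and adjusted p = 0.559 with an estimated correlation). Bcl6 (1.38 ± 0.16), Tigit (5.12 ± 0.31), an inhibitory receptor, and Tox (2.03 ± 0.20), a nuclear factor of chronically stimulated T cells, rose. Cd40lg (-2.24 ± 0.18), Il6ra (-1.74 ± 0.20), the IL6 receptor, Slc26a11 and Slamf6 fell. Of 16 naive genes 14 fell, and all 16 adjusted over the list alone (camera adjusted p = 1.57e-12, and adjusted p = 0.0679 with an estimated correlation), among them Klf2 (-3.20 ± 0.21) and Tcf7 (-2.25 ± 0.14). Of 10 CD8 and natural killer genes 6 fell, including the receptors Klrk1 (-6.77 ± 0.61) and Klrd1 (-5.96 ± 0.63), with 1 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.0468, and adjusted p = 0.564 with an estimated correlation). Proliferation genes rose in 8 of 24 cases and in 13 adjusted over the list alone (camera adjusted p = 7.59e-06, and adjusted p = 0.772 with an estimated correlation). Glycolysis genes rose in 5 of 16, with 9 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0348, and adjusted p = 0.559 with an estimated correlation). Among effector genes Il1rl1 (3.31 ± 0.22) and Ccr6 (1.77 ± 0.21) rose and Runx3, Cxcr6 (-3.54 ± 0.45), a chemokine receptor, Il12rb2 and Id2 fell. Genes with the largest changes included Tnfrsf8 (CD30, 7.47 ± 0.41, 62.3 ± 2.14 against 0.3 ± 0.02 TPM) and the integrin gene Itgb8 (7.44 ± 0.49). Others were Il1r2, the decoy receptor of IL1 (8.33 ± 0.98), Penk (9.18 ± 1.55) and Vipr1, a neuropeptide receptor (-5.07 ± 0.21).

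Between these populations edgeR called 1907 of 13064 genes, 1030 higher and 877 lower in Tfr cells (859 and 479 by at least 2-fold). DESeq2 called 3380 and limma 2131. In a run without the Tfh MUT and Tfr libraries, chosen after seeing the data, the count was 4938. The count with all 8 libraries, 1907, fell to 267 without non-Tfh, 80 without non-Tfh MUT, 1128 without Tfr, 1139 without Tfr MUT, 1064 without CD4+ and 1057 without CD4+ MUT, and rose to 4028 without Tfh and 4119 without Tfh MUT.

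Tfh cells differed from CD4+ T cells (a label with no further sort) more widely (n = 2 libraries per side). All 16 naive genes fell, also adjusted over the list alone (camera adjusted p = 1.11e-11, and adjusted p = 0.0726 with an estimated correlation). Igfbp4, an IGF-binding protein gene, changed by -8.86 ± 0.57 (4 ± 2.38 against 1484 ± 393 TPM), Lef1, a transcription factor of early and naive T cells, by -2.95 ± 0.17, and Ccr7, the lymph node homing chemokine receptor, by -2.88 ± 0.22 (edgeR adjusted p = 0.00101). Of the Tfh programme 19 genes rose and 1 fell, and 20 and 1 adjusted over the list alone (camera adjusted p = 5.2e-10, and adjusted p = 0.139 with an estimated correlation). Cxcr5 and Pdcd1 in this list encode sorting markers that the non-Tfh and Tfr labels state. The Tfh and CD4+ labels state no such sort, so how far these 2 follow from sorting is unknown. Maf, a transcription factor that promotes IL21, rose by 6.44 ± 0.20, Icos, a costimulatory receptor, by 2.75 ± 0.18 and Bcl6 by 2.14 ± 0.16. Regulatory genes rose in 18 of 20 cases and fell in 1, with the same counts adjusted over the list alone (camera adjusted p = 6.77e-09, and adjusted p = 0.362 with an estimated correlation). Effector helper genes rose in 15 of 19 cases and in 16 adjusted over the list alone (camera adjusted p = 1.23e-09, and adjusted p = 0.362 with an estimated correlation). Tbx21, the T-bet gene of Th1 cells, rose by 7.55 ± 0.52 (41.9 ± 11.8 against 0.2 ± 0.08 TPM), Cxcr3, a chemokine receptor of Th1 cells, by 9.62 ± 0.59 and Ccl5, a chemokine, by 9.28 ± 0.83. Of 24 proliferation genes 14 rose, and 21 adjusted over the list alone (camera adjusted p = 4.46e-06, and adjusted p = 0.802 with an estimated correlation). Of 16 glycolysis genes 9 rose, also adjusted over the list alone (camera adjusted p = 0.00376, and adjusted p = 0.362 with an estimated correlation). Ribosome biogenesis genes had a median of -0.31, with 1 higher and 2 lower, and 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0468, and adjusted p = 0.805 with an estimated correlation). The calcium-binding protein gene S100a4 (10.59 ± 0.81, 635 ± 363 against 0.28 ± 0.28 TPM) and Gzmk (10.38 ± 0.56) were among the largest increases, and Sorcs2, a sorting receptor gene (-7.23 ± 0.26), among the largest decreases. B identity genes had a median TPM of 7.9 in CD4+ and 8.7 in CD4+ MUT, below every Tfh, Tfr and non-Tfh library. edgeR called 3453 of 13064 genes, 1994 higher and 1459 lower in Tfh cells (1598 and 636 by at least 2-fold), DESeq2 4640 and limma 3672. Without the Tfh MUT and Tfr libraries, chosen after seeing the data, edgeR called 5484. The count fell to 772 without CD4+, 1006 without CD4+ MUT, 2144 without non-Tfh and 2160 without non-Tfh MUT, and rose to 5423 without Tfh.

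Activated non-Tfh cells differed from CD4+ T cells mostly by gains, led by effector helper genes (n = 2 libraries per side). Of 19 such genes 15 rose, and all 19 adjusted over the list alone (camera adjusted p = 8.19e-25, and adjusted p = 0.126 with an estimated correlation). Tbx21 rose by 7.96 ± 0.52 (49.7 ± 10.7 against 0.2 ± 0.08 TPM, edgeR adjusted p = 0.00308), Cxcr3 by 9.15 ± 0.59, Ccr2 by 8.30 ± 0.39 and Id2, an inhibitor of E proteins, by 2.05 ± 0.30. The Tfh programme rose in 8 of 22 cases and in 15 adjusted over the list alone (camera adjusted p = 3.48e-10, and adjusted p = 0.126 with an estimated correlation). Maf rose by 5.21 ± 0.19 and Icos by 1.73 ± 0.18. Regulatory genes rose in 6 of 20 cases, with 12 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.64e-08, and adjusted p = 0.471 with an estimated correlation). They included Ctla4 (3.26 ± 0.29) and Il2rb (3.97 ± 0.32), the beta chain of the IL2 receptor. Naive genes fell in 5 of 16 cases, in 11 adjusted over the list alone (camera adjusted p = 1.41e-08, and adjusted p = 0.124 with an estimated correlation). Lef1 changed by -1.47 ± 0.16. Changes outside the lists included the rise of S100a4 (9.36 ± 0.80) and of Lgals3, a galectin (8.42 ± 0.77). They also included the fall of Sorcs2 (-2.94 ± 0.20), Vipr1 (-1.66 ± 0.18) and Sox4, a transcription factor (-2.40 ± 0.30). Camera also called proliferation (median 0.49, camera adjusted p = 0.0157, and adjusted p = 0.9 with an estimated correlation) and ribosome biogenesis (median -0.28, camera adjusted p = 0.0147, and adjusted p = 0.9 with an estimated correlation), in which edgeR passed no member. Under an unadjusted p of 0.05 lay 4 and 2 members, DESeq2 called 2 and 0, and limma 0 in both. In total edgeR called 503 of 13064 genes, 422 higher and 81 lower (390 and 53 by at least 2-fold), DESeq2 1207 and limma 406. Without the Tfh MUT and Tfr libraries, chosen after seeing the data, edgeR called 3134. The count fell to 31 without non-Tfh, 74 without non-Tfh MUT, 58 without CD4+ and 111 without CD4+ MUT, and rose to 1155 without Tfh and 1203 without Tfh MUT.

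The labels name no gene for the MUT mark, so no targeted gene could be looked up. Across the 4 populations edgeR called no gene between MUT and unmarked libraries (0 of 13064, 192 under an unadjusted p of 0.05), DESeq2 called 2 and limma 0 (n = 4 libraries per side). The label term fits a change common to all 4 populations. The count of 0 thus does not rule out changes that run the other way in the Tfh pair. Interferon response genes had a median log2 fold change of 0.28 and were called by camera (camera adjusted p = 0.00313, and adjusted p = 0.881 with an estimated correlation), as were heat shock genes with 0.22 (camera adjusted p = 7.2e-05, and adjusted p = 0.355 with an estimated correlation). By population, from 1 library per label, the interferon median was 0.61 in the CD4+ pair, 0.45 in non-Tfh and 0.77 in Tfr, and -0.94 in Tfh. No single member of either list passed by edgeR, with 0 and 2 under an unadjusted p of 0.05 and 0 called in both by DESeq2 and by limma. Leaving out both the Tfh MUT and Tfr libraries, chosen after seeing the data, gave 478 genes. Without the Tfh library alone the count was 24, and without Tfh MUT alone it was 29.

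**Figure D2:**
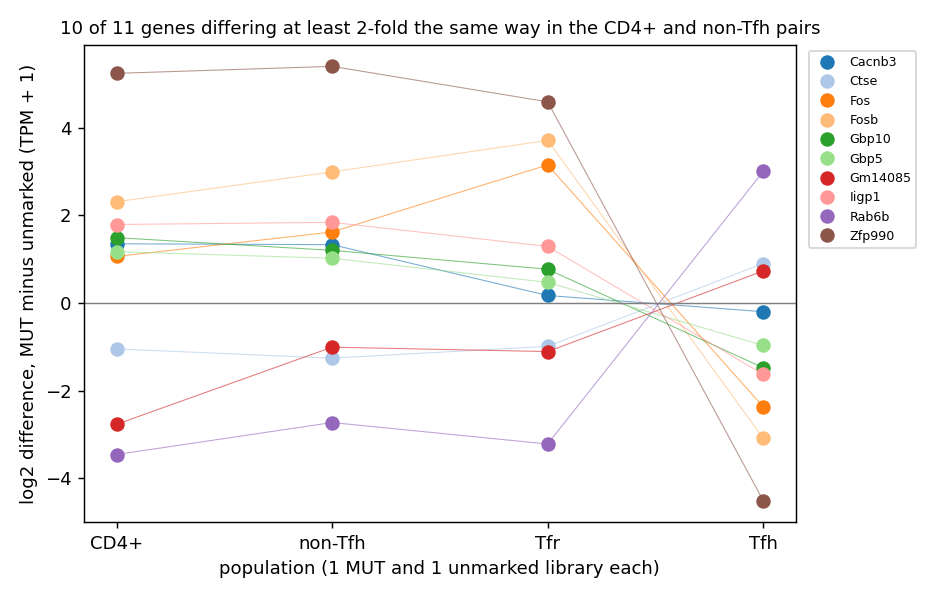
Log2 difference of TPM + 1, MUT minus unmarked (vertical axis), of 10 genes (lines) in the CD4+, non-Tfh, Tfr and Tfh pairs (horizontal axis), 1 library per label and population, chosen from 11 that differed at least 2-fold the same way in the CD4+ and non-Tfh pairs. Zfp990 stands at 5.24, 5.40 and 4.59 in the first 3 pairs and at -4.51 in Tfh.

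ConA activation was compared with the CD4+ and CD4+ MUT libraries by a rule of size without a test, as there was a single ConA library. Gzmb, the granzyme B gene, reached 872 TPM against at most 0.08, Il2ra, the alpha chain of the IL2 receptor, 445 against at most 0.62, and Tnfrsf9, the costimulatory receptor 4-1BB, 982 against at most 10.2. Csf2, the GM-CSF gene, stood at 112 TPM against at most 0.22. By the rule (a log2 difference of at least 2 from both comparison libraries and TPM of at least 10) 783 genes differed, 454 higher and 329 lower. With TMM-scaled CPM in place of TPM the count was 1008, 826 higher and 182 lower. The median of all expressed genes lay at -0.30 on the log2 TPM scale and 0.26 on the CPM scale, so list medians are read against those values. Proliferation genes were higher in 15 of 24 cases (median log2 difference 2.52, percentile 100 of 10000 random lists matched on expression), with Mki67 at 95 TPM against 6.23 and 7.56. Glycolysis genes were higher in 9 of 16 (median 2.15, percentile 100), such as Hk2, hexokinase, with 51.8 TPM against 2.28 and 2.73. Cholesterol synthesis genes were higher in 5 of 17 (median 1.31), effector genes in 5 of 14 (median 1.67) and regulatory genes, many of which mark activation, in 9 of 18 (median 2.45), while Foxp3 was at 6.31 TPM. Of 5 CD8 and natural killer genes Eomes was higher by the rule and Prf1, the perforin gene, lower (log2 differences of 5.13 and -2.30). Naive genes were lower in 7 of 16 (median -1.80), Klf2 with 17.9 TPM against 805 and 625. Interferon response genes were lower in 8 of 20 (median -2.25, percentile 0). B identity genes were lower in 8 of 20, with Cd79a at 0.84 TPM against 34.4 and 35.3. The medians of the Tfh programme (-0.14), immediate early (-0.11) and ribosome biogenesis (-0.07) lists turn positive on the CPM scale (0.46, 0.49 and 0.53). Tgoln2 and Entpd4b were listed at 0 in the 4 libraries with the larger length minus effective length, ConA among them, and at no less than 2.18 and 6.51 TPM in the other 18. Their difference follows that quantity, and H2-L, Ly6c1, Ifi208 and Ifi209 have near-identical relatives among which reads can be split, so all 6 are reported as uncertain. Entpd4 ran the other way, at 28.8 to 63.3 TPM in those 4 libraries and at most 24.6 in the other 18. Other genes raised or partly shifted with that quantity were not searched for, and the ConA counts can hold some.

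Activated B cells were set against splenic B cells by the same size rule, required in all 6 cultures. Genes of DNA replication and division were higher in the cultures. Uhrf1, which copies DNA methylation at replication, stood at 125 to 387 TPM against 16.2, Gins2, of the replicative helicase, at 41.4 to 129 against 5.84, and Mybl2, a cell cycle transcription factor, at 37 to 146 against 5.23. All 24 proliferation genes had a positive mean log2 difference (median 2.90, percentile 100 of random lists), although by the rule, which asks for every culture, 2 of them passed. Cholesterol synthesis passed in 4 of 17 genes (median 1.66), including Fdps, a synthase of the mevalonate pathway, with 37 TPM in splenic B cells and at least 213 in each culture. Medians of ribosome biogenesis (1.29) and glycolysis (1.39) lay at percentile 100 as well, but 0 of 20 and 0 of 16 members passed the rule, and ribosome members differed between cultures (Utp20 by -1.33 to 1.62). The median of IL4 response genes (0.79, 0 of 14 passing) lay at percentile 99.99 over cultures of which 2 had IL4, with Cish at log2 differences of -0.47 to 7.78. That of class switching genes (0.52, 1 of 17) lay at 99.43. Medians were low for resting B genes (-2.21, 3 of 18 lower by the rule), B identity (-1.36, 1 of 22), MHC class II (-1.99, 0 of 10) and interferon response (-1.11, 0 of 20, percentile 0.09). Interferon members went both ways between cultures, with Isg15 at log2 differences of -2.29 to 3.29. Cr2, the complement receptor of mature B cells, had 629 TPM in splenic B cells and 9.5 to 137 in the cultures. Immediate early genes were lower in 3 of 18 (median -0.79), with Fos at 277 TPM in splenic B cells and at most 8.96 in the cultures. Macrophage transcripts were present in the splenic library: C1qa, a complement gene of macrophages, stood at 79.7 TPM and at most 0.54 in the cultures, Slc40a1, the iron exporter ferroportin, at 82.5 and at most 0.29, and 8 of 16 myeloid genes were lower in the cultures. In all, 140 genes met the rule, 28 higher and 112 lower. As all 6 differences share the splenic library, 20 simulations of unchanged groups gave 2.9 higher and 1.05 lower on average. The median of all expressed genes was -0.22. Leaving out the aCD40+IL4 culture raised the count to 295.

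**Figure D3:**
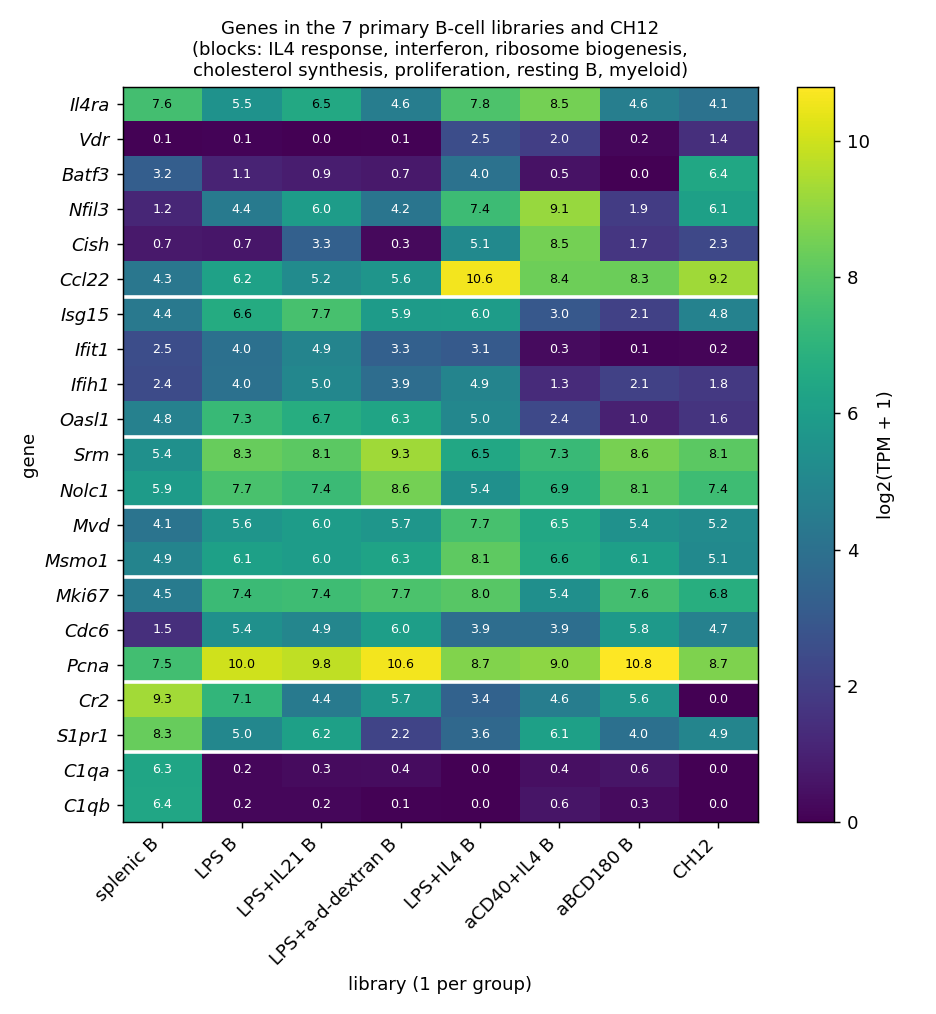
Levels of 21 genes (vertical axis) in the 7 primary B-cell libraries and CH12 (horizontal axis, 1 library per group), coloured and printed as log2(TPM + 1), with blocks of IL4 response, interferon, ribosome biogenesis, cholesterol synthesis, proliferation, resting B and myeloid genes. Vdr stands at 2.0 to 2.5 in both cultures with IL4 and at most 0.2 in the other 4 cultures, and C1qa at 6.3 in splenic B cells and at most 0.6 in every culture.

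Within the 6 cultures, those with IL4 in the label (n = 2) were compared with those without (n = 4), with LPS as a covariate. IL4 response genes were higher as a list (median log2 fold change 1.86, camera adjusted p = 1.9e-06, and adjusted p = 0.407 with an estimated correlation), and 6 of 15 rose adjusted over the list alone. They included Vdr, the vitamin D receptor (5.85 ± 0.80), Batf3, a basic leucine zipper factor (4.40 ± 0.70), and Il4ra, the IL4 receptor (2.90 ± 0.70, 294 ± 102 against 45 ± 31.1 TPM). Over all genes no member of this list passed by edgeR (smallest adjusted p 0.117), with 8 under an unadjusted p of 0.05, 6 called by DESeq2 and 0 by limma. The 5 genes that edgeR did call, of 12515, all rose, each at an adjusted p of 0.0412: Ptgs1, cyclooxygenase 1 (8.24 ± 0.66), Serpinb6b, a protease inhibitor (5.39 ± 0.47, 53.3 ± 24.3 against 1.32 ± 0.42 TPM) and Atp11a, a phospholipid flippase (4.16 ± 0.35). Those 5 also held Klhdc2, of a ubiquitin ligase (3.59 ± 0.25, 471 ± 222 against 34 ± 6.22 TPM), and Htr7, a serotonin receptor, which falls outside the rule for named genes and was chosen after its values were seen. Ribosome biogenesis genes were lower (median -1.504, camera adjusted p = 1.95e-11, and adjusted p = 0.719 with an estimated correlation), 16 of 20 adjusted over the list alone, such as Srm, spermidine synthase (-1.76 ± 0.46), and Nolc1, a nucleolar protein (-1.93 ± 0.52). Proliferation genes were lower (median -0.64, camera adjusted p = 2.5e-06, and adjusted p = 0.719 with an estimated correlation), 4 of 24 adjusted over the list alone, among them the replication clamp Pcna (-1.54 ± 0.34). Cholesterol synthesis was higher (median 0.99, camera adjusted p = 2.5e-06, and adjusted p = 0.719 with an estimated correlation), 9 of 17 adjusted over the list alone, with the mevalonate pathway enzyme Mvd at 1.61 ± 0.30. MHC class II (median 1.78, camera adjusted p = 0.000597, and adjusted p = 0.719 with an estimated correlation) and glycolysis (median 0.79, camera adjusted p = 0.0212, and adjusted p = 0.786 with an estimated correlation) were higher. Heat shock (median -0.46, camera adjusted p = 0.0112, and adjusted p = 0.719 with an estimated correlation) and erythroid genes (median -2.93, camera adjusted p = 0.0142, and adjusted p = 0.719 with an estimated correlation) were lower. In the LPS+IL4 culture Hba-a1, an alpha globin gene with a near-identical copy, had 0.17 TPM against 4435 in aCD40+IL4 and at least 873 in the other cultures. Under an unadjusted p of 0.05 lay 1547 genes, DESeq2 called 493 and limma 0. With the suffix of the library number (A or C) as a covariate, edgeR called 0 genes for IL4. The edgeR count was 0 without LPS, without LPS+IL4 or without LPS+a-d-dextran, 13 without LPS+IL21, 68 without aCD40+IL4 and 66 without aBCD180.

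Cultures with LPS in the label (n = 4) held more interferon response transcripts than those without (n = 2). Isg15, a ubiquitin-like antiviral protein, stood at 59.6 to 201 TPM in the 4 LPS cultures against 3.22 in aBCD180 and 6.79 in aCD40+IL4, a log2 fold change of 4.48 ± 0.86. Ifit1, which binds foreign RNA (6.55 ± 1.09), and Ifih1, the RNA sensor MDA5 (3.37 ± 0.64), were higher too. The list median was 2.29 (camera adjusted p = 4.72e-12, and adjusted p = 0.639 with an estimated correlation), and 5 of 20 genes rose adjusted over the list alone. Over all 12515 genes edgeR called 0 (507 under an unadjusted p of 0.05, smallest adjusted p 0.598), DESeq2 163 and limma 0. Camera also called higher values of glycolysis (median 0.71, camera adjusted p = 6.62e-06, and adjusted p = 0.639 with an estimated correlation), and cholesterol synthesis (0.47, camera adjusted p = 0.000206, and adjusted p = 0.639 with an estimated correlation). So it did for proliferation (0.93, camera adjusted p = 0.000101, and adjusted p = 0.639 with an estimated correlation) and plasma cell genes (0.27, camera adjusted p = 0.000142, and adjusted p = 0.639 with an estimated correlation). It called lower values of ribosome biogenesis (-0.43, camera adjusted p = 0.00199, and adjusted p = 0.639 with an estimated correlation), T identity (-0.70, camera adjusted p = 0.00229, and adjusted p = 0.639 with an estimated correlation) and erythroid genes (-2.39, camera adjusted p = 0.034, and adjusted p = 0.639 with an estimated correlation). In these 7 lists edgeR passed no member over all genes, with 6, 2, 2, 5, 0, 2 and 0 members of the proliferation, glycolysis, cholesterol, plasma cell, ribosome, T identity and erythroid lists under an unadjusted p of 0.05. DESeq2 called 3 plasma cell genes, 1 T identity gene and 1 erythroid gene, and limma 0 in any of them. The median erythroid TPM was 0.17 in LPS+IL4, but 26.2 in LPS, 35.94 in LPS+a-d-dextran and 86.91 in LPS+IL21. It was 50.78 in aCD40+IL4 and 58.45 in aBCD180, so the lower erythroid value leans on the LPS+IL4 library. Without the aBCD180 culture edgeR called 2 genes for LPS.

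The 7 primary B libraries and the 9 CD4 T libraries were separated by their lineage genes. All 22 B identity genes were higher in B cells, over all genes and adjusted over the list alone (camera adjusted p = 6.31e-15, and adjusted p = 0.155 with an estimated correlation). Pax5, the transcription factor that commits cells to the B lineage, rose by 5.66 ± 0.72 (369 ± 142 against 8.22 ± 9.2 TPM, edgeR adjusted p = 1.83e-05) and Cd79a, of the B-cell receptor complex, by 4.66 ± 0.70. All 24 T identity genes were lower, likewise adjusted over the list alone (camera adjusted p = 2.2e-28), and this call held with an estimated correlation (adjusted p = 0.00421). Cd3e, of the T-cell receptor complex, changed by -9.69 ± 0.80 (0.77 ± 0.79 against 659 ± 161 TPM), and Tcf7 by -8.30 ± 0.64. All 10 MHC class II genes rose, also adjusted over the list alone (camera adjusted p = 2.68e-06, and adjusted p = 0.18 with an estimated correlation), with Cd74, the invariant chain, at 3.78 ± 0.60. Of 24 proliferation genes 19 rose, and 22 adjusted over the list alone (camera adjusted p = 6.86e-05, and adjusted p = 0.39 with an estimated correlation), such as the helicase subunit Mcm3 (2.03 ± 0.42). Of the 7 B libraries 6 were activated cultures, while ConA was the 1 activated culture among the 9 T libraries. Activation thus runs with lineage and cannot be told apart from it here. The proliferation median was also higher in activated than in splenic B cells (2.90) and in ConA than in CD4+ T cells (2.52). Of 22 plasma cell genes 13 rose by both adjustments, that is over all genes and adjusted over the list alone (camera adjusted p = 2.15e-05, and adjusted p = 0.173 with an estimated correlation). Naive T-cell genes fell in 9 of 16 cases and rose in 1, with 9 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.00106, and adjusted p = 0.39 with an estimated correlation). Interferon response genes fell in 8 of 20 and rose in 1, also adjusted over the list alone (camera adjusted p = 0.00135, and adjusted p = 0.39 with an estimated correlation), with Ifit2 at -2.24 ± 0.40 and Oasl1, the gene that rose, at 2.66 ± 0.80. Resting B genes went both ways, 4 higher and 6 lower, and 5 and 6 adjusted over the list alone, with a median of -0.84, a mean of 0.16 and a camera adjusted p of 0.475. Among the other genes Havcr1 (TIM1, 9.88 ± 1.00) was higher in B cells, and Cd40lg (-10.94 ± 0.65) and the chemokine receptor Ccr8 (-12.87 ± 1.74) lower. In total edgeR called 5773 of 12437 genes, 2971 higher and 2802 lower in B cells (1429 and 1820 by at least 2-fold), DESeq2 7241 and limma 5016. Median B identity TPM was highest among the T libraries in Tfh MUT and Tfr (37.9 and 34.3), and without both, chosen after seeing the data, 5202 genes were called. Without the 4 MUT libraries the count was 3263.

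CH12 was set against all 7 primary B libraries by the size rule, with no replicate check. The line expressed genes that the primary cells held at low levels. Madcam1, the mucosal addressin of endothelium, reached 192 TPM against at most 0.44, Rgs13, a regulator of G-protein signalling typical of germinal centre B cells, 547 against at most 8.57, and Wwtr1, the Hippo pathway coactivator TAZ, 57.6 against at most 0.1. Cd5, a receptor of T cells and B-1 cells, was higher by the rule (54.3 TPM), as was Fkbp11, a chaperone of secretory cells (91.5 TPM). Rgs13 and Fkbp11 did not stand for their lists. In the germinal centre and class switching list 1 of 17 genes was higher by the rule (median -0.31, percentile 16.26, 7 members above 0). In the plasma cell list 1 of 22 was (median 0.12, percentile 84.45, 13 members above 0). Lower by the rule were Fcer2a, the low-affinity IgE receptor (0.23 TPM against at least 57.3), Mtap, which salvages methionine (0.01 against at least 36.7), Klf2 and Bach2, transcription factors of resting lymphocytes (1.31 and 4.77 TPM), and Cd2, an adhesion receptor (0.06 TPM). List medians were low for B identity (-1.35, 2 of 22 lower by the rule), MHC class II (-1.42, 0 of 10), resting B (-0.97, 2 of 18), interferon response (-1.39, 0 of 20), cholesterol synthesis (-1.22, 0 of 17) and erythroid genes (-4.47, 1 of 11), each at percentile 0.01 or below of random lists. Many members were above some primary libraries and below others, such as H2-Oa (-2.80 to 2.40). The proliferation median was 0.51 (percentile 99.99), but 0.06 (percentile 86.86) against the 6 cultures alone, a set chosen after seeing the data, so it rests on the unstimulated splenic library. The medians of ribosome biogenesis (0.02) and NF-kB target genes (0.03) were near 0 and turned negative on the CPM scale (-0.04 and -0.04). By the rule 300 genes differed, 222 higher and 78 lower.

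The 3 brain regions differed in genes of their resident neurons, read by the size rule from 1 library each. In the putamen 17 of 19 striatal genes were higher than in both other regions (median log2 difference 4.25, percentile 100 of random lists). Adora2a, the adenosine receptor of indirect-pathway neurons, stood at 492 TPM against 1.62 in the medulla and 19.9 in the cortex, Drd1, the dopamine receptor of direct-pathway neurons, at 195 against 0.5 and 11.8, and Six3, a homeobox factor of the developing striatum, at 51.9 against 0.01 and 1.8. In the medulla 19 of 24 Hox genes were higher (median 4.10), with Hoxb5, which specifies posterior position, at 155 TPM against at most 1.66. Hindbrain neuron genes were higher in 11 of 20 cases (median 3.08), such as the glycine receptor Glra1 (120.1 TPM against 3.76 and 0.35) and the glycine transporter Slc6a5 (130.2 against 5.69 and 0.1). The oligodendrocyte list had a median of 1.54 there (0 of 15 by the rule) and the astrocyte list 0.88 (2 of 11 by the rule). Gfap, the astrocyte filament, stood at 2139 TPM against 115 and 159. Of the 11 astrocyte genes 9 lay above 0, while Slc1a3 (-0.90) and Slc1a2 (-0.66) were lower. In the sensorimotor cortex 7 of 17 excitatory neuron genes were higher (median 2.91). Slc17a7, the vesicular glutamate transporter, stood at 1271 TPM against 101 in the putamen and 70 in the medulla, and Emx1, a homeobox factor of the dorsal forebrain, at 61.2 against 1.74 and 0.41. Vip and Cck, neuropeptide genes, were the 2 of 13 GABAergic genes higher by the rule. The GABAergic median in the cortex was 0.64, with 11 of 13 members above 0, while Gad2 (-0.71) and Slc32a1 (-1.04) were lower. Immediate early genes had a median of 0.86 there. In the putamen the GABAergic median was 0.82 and the pan-neuronal median -0.99, and the putamen also held genes of intestine, such as Apoa4, an apolipoprotein, at 512 TPM against 18.5 and 0.93. The rule gave 160 genes for the putamen, 134 for the medulla and 88 for the cortex.

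**Figure D4:**
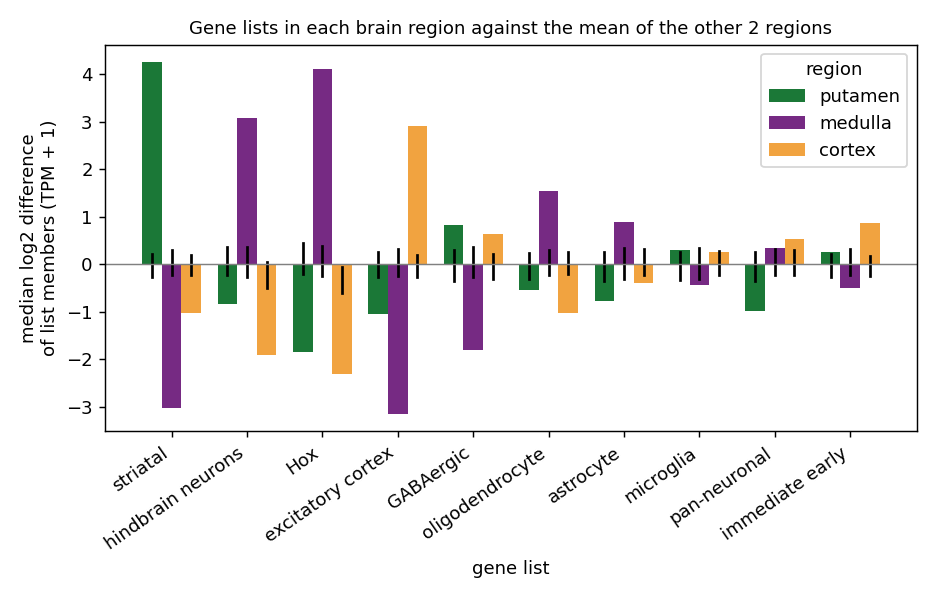
Median log2 difference of TPM + 1 (vertical axis) of 10 gene lists (horizontal axis) in the putamen (green), medulla (purple) and cortex (orange), each against the mean of both other regions, 1 library per region, with black lines for the central 95% of 10000 random lists matched on expression. The striatal list stands at 4.25 in the putamen, the Hox list at 4.10 in the medulla and the excitatory list at 2.91 in the cortex.

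Basophils and back skin were each set against all other libraries, with a log2 difference of at least 3 required from every one. Basophils expressed 12 of 18 basophil genes above all 21 others (median 9.38). Mcpt8 and Prss34, basophil proteases, reached 12997 and 13374 TPM against at most 5.08 and 2.36 elsewhere, Ms4a2, the beta chain of the IgE receptor, 1382 and Gata2, a factor of basophil and mast cell development, 1761. Myeloid genes were higher in 6 of 16 cases (median 3.44), among them S100a8 and S100a9. Ly6g, a granulocyte gene, reached 838 TPM against at most 0.29 elsewhere, and Ctsg, a protease gene, 851 against at most 0.98. Whether basophils or other cells in the library held these transcripts was not tested. Mast cell genes were higher in 3 of 9 cases (median 1.46). Those 3 were Cma1, a chymase, Tpsb2, a tryptase, and Slc18a2, the vesicular amine transporter. The library also held milk protein transcripts, such as Wap (314 TPM) and Csn1s2a (284 TPM), whose source was not tested. B and T identity lists had medians of -3.60 and -3.69. Back skin expressed the genes of hair and epidermis. Hair follicle genes passed in 16 of 18 cases (median 10.36), with the inner root sheath keratin Krt71 at 10038 TPM and Tchh, trichohyalin, at 8786 against at most 5.72 elsewhere, and epidermal genes in 16 of 18 (median 8.12), with the basal keratin Krt14 at 2747. Skeletal muscle genes passed in 11 of 12 (median 6.93), such as Acta1, muscle actin (1846 TPM), adipocyte genes in 8 of 10 (median 7.06), such as Adipoq, adiponectin (199), and dermal fibroblast genes in 8 of 13 (median 7.39), such as the collagen gene Col1a1 (642). The 5 melanocyte genes had a median of 2.70 and did not pass the rule. Keratin-associated protein genes, among the largest differences in skin, belong to a family of near-identical copies and are uncertain. The median of all expressed genes was -0.25 for basophils and -0.71 for skin (0.03 and -0.46 on the CPM scale), and the rule gave 133 and 541 genes.

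Because the series concerns transcription factors, the library with the highest TPM was found for each of 63 lineage factors. The highest library was a B-cell library for 7, a CD4 T library for 15, basophils for 6, a brain region for 20 and back skin for 15. Factors highest in a single lineage included Foxp3, at 579 TPM in Tfr MUT and at most 0.4 outside the T cells, Tbr1, of deep-layer cortical neurons, at 95.2 in the cortex and at most 0.1 outside the brain, Hoxc13, of the hair shaft, at 142 in skin and at most 0.14 elsewhere, and Tcf7, at 1682 in CD4+ and at most 32.1 outside the T cells. Pax5 was highest in aCD40+IL4 B cells (584 TPM), and the next lineage was the Tfh MUT library with 28.2. Several factors were shared. Bcl6 was at 84.8 TPM in Tfh and 76 in splenic B cells, Prdm1, a factor of plasma cells and regulatory T cells, at 43.4 in skin and 39.8 in Tfr MUT, and Batf at 462 in Tfr MUT and 424 in LPS+IL4 B cells. Each of these ratios compares single libraries and carries no replicate error.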

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

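The test of exchanged Tfr and Tfh MUT labels, the fit with exchanged Tfh pair labels and the counts over other splits of the libraries were chosen only after the result was seen. MUT and unmarked libraries differed in opposite directions in Tfh and Tfr cells. The median log2 difference of B identity genes, MUT minus unmarked, was 2.17 in Tfh and -1.74 in Tfr, that of MHC class II genes 2.17 and -1.73, and that of proliferation genes 1.11 and -0.82, from 1 library each, and the difference between the populations was not tested.

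RNA of B cells in the libraries labelled Tfh MUT and Tfr is a candidate explanation. The label gives a CD4 gate for Tfr, which is meant to leave B cells out. Tfr MUT, labelled with the same gate, still held Cd79a at 41.3 TPM, so the gate does not settle the question. Of 59 genes abundant in B cells and outside the fixed B-cell lists, 86.4% were higher in Tfh MUT than in Tfh and 81.4% higher in Tfr than in Tfr MUT (45.4% and 65.0% of all genes at a TPM of at least 1 in either library), with Cd79a at 234 and 171 TPM in those libraries. The 59 held 5 erythroid genes, and proliferation genes were not left out of them. Proliferation medians were also higher in Tfh MUT than in Tfh and in Tfr than in Tfr MUT. The shares may thus not come from B-cell genes alone. An exchange of the Tfr and Tfh MUT labels is argued against by a Treg programme median 1.59 log2 units higher in Tfr. An exchange of the mutant label within the Tfh pair may also play a part, since of 11 genes that differed at least 2-fold the same way in the CD4+ and non-Tfh pairs, 0.0% kept their direction in the Tfh pair and all 11 did in the Tfr pair. Of genes that differed at least 2-fold in both the Tfh and Tfr pairs, 248 ran opposite ways and 0 the same way. Between the non-Tfh and Tfr pairs 19 ran the same way and 0 opposite. Zfp990 stood at 28.46 TPM in Tfh and 0.29 in Tfh MUT, but at 0.06 in Tfr and 24.45 in Tfr MUT. These values go with an exchange in the Tfh pair, from 1 library per label. A biological difference of the mutation between Tfh and Tfr cells was not tested and stays open, as opposite directions alone do not forbid it.

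With the mutant labels of the Tfh pair exchanged, edgeR called 72 genes for the label, 59 higher and 13 lower, against 0 with the labels as given (192 under an unadjusted p of 0.05, DESeq2 2, limma 0), and interferon response genes had a median of 0.75 with 7 of 20 higher (camera adjusted p = 2.93e-18, and adjusted p = 0.439 with an estimated correlation). That exchange is also the highest of the 8 splits of the label within pairs, which are too few for a share under 0.05. For B against CD4 T cells, 1 of 100 splits of the 16 libraries, the real split, called as many as 5773 genes, and the highest other called 467. The real split follows 2 lineages that the labels already set apart, and the other splits mix them. These counts therefore show that lineage outweighs mixed groupings, and no conclusion about chance is drawn.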

How the results depend on the processing

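The alternatives without the Tfh MUT and Tfr libraries, with the B identity level as a covariate, with the Tfh pair's labels exchanged, with the lower length offset only, with LPS+IL4 or LPS+IL21 alone, and CH12 against 2 libraries or the 6 cultures were chosen after seeing the data. RLE size factors left every count within 1.5 times of its value. Other settings moved counts, and the cause was not tested. Without the filter, Tfr against Tfh gave 99 genes and IL4 21. DESeq2 gave 2 for the mutant label, 2351 for Tfh against non-Tfh, 632 for Tfr against Tfh, 3380 for Tfr against non-Tfh, 1207 for non-Tfh against CD4+, 493 for IL4 and 163 for LPS. Limma gave 109 for Tfr against Tfh and 0 for IL4 (edgeR 5, with 1547 under an unadjusted p of 0.05). Without the mutant label as a covariate Tfh against non-Tfh gave 1500 and Tfr against Tfh 138. IL4 gave 3 without the LPS covariate and 0 with the library suffix as a covariate. B against CD4 T cells gave 3263 without the 4 MUT libraries, which leaves fewer samples.

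Without the Tfh MUT and Tfr libraries the counts were 478 for the mutant label, 3221 for Tfh against non-Tfh, 1033 for Tfr against Tfh, 4938 for Tfr against non-Tfh, 5484 for Tfh against CD4+ and 3134 for non-Tfh against CD4+. With the B identity level as a covariate they were 1651 for Tfh against non-Tfh, 631 for Tfr against Tfh, 3184 for Tfr against non-Tfh and 1584 for non-Tfh against CD4+. With the labels of the Tfh pair exchanged they were 72 for the mutant label, 2129, 364, 3413 and 1001 for the same 4 contrasts. Leaving out 1 library at a time gave 0 to 29 genes for the mutant label, 0 to 3561 for Tfh against non-Tfh, 0 to 458 for Tfr against Tfh, 80 to 4119 for Tfr against non-Tfh, 772 to 5423 for Tfh against CD4+, 31 to 1203 for non-Tfh against CD4+, 0 to 68 for IL4, 0 to 2 for LPS, 140 to 295 for activated against splenic B cells and 863 to 902 for ConA.

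By size rule, activated against splenic B cells gave 997 with LPS+IL4 alone and 721 with LPS+IL21 alone, which ask for 1 culture in place of 6, and an edgeR fit of 6 against 1, whose spread comes from the 6 cultures alone, called 71. CH12 gave 498 at a TPM minimum of 1 and 501 against 2 libraries, and 334 against the 6 cultures. Brain, basophil and skin counts stayed within 1.5 times under CPM, a pseudocount of 0.1 and a TPM minimum of 1. Of 138 list tests camera called 55, and 1 with an estimated correlation, while fry called 26. For 104 fold changes of named genes under these alternatives and leave-outs, 1319 recomputed values stayed on their side of the threshold, 188 were no longer past it and 23 newly passed. Among values past the threshold in the main fit or the alternative, 0 changed direction. Direction was not compared for values past it in neither.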

Other observations

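The milk list in this part and 6 of the intestinal genes in the test of carry-over were chosen only after the result was seen. The basophil library held transcripts of milk proteins, and whether they came from basophils was not tested: Csn2, a casein, stood at 356 TPM, Glycam1, a mucin of mammary gland and vessels, at 259 and Csn1s1, a further casein, at 151. Of 8 milk genes 7 were more than 4 times their level in every other library. Heat shock genes had a median of 1.35 in activated against splenic B cells, while Hspa1a and Hspa1b, inducible chaperones with near-identical sequences, were lower by the size rule.

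The putamen library held intestinal transcripts, with Apoa1, an apolipoprotein, at 591 TPM and Fabp2 and Fabp1, fatty acid-binding proteins of enterocytes and liver, at 457 and 319. RNA of intestine is a candidate explanation, as 88.5% of 26 intestinal genes were at least 4 times their level in both other regions (list median 29.1 TPM against 1.9 in the medulla and 0.14 in the cortex). Carry-over from another library of this series is argued against, since 6.9% of 29 genes were higher in any other library, with 8.7% of the 23 that passed in that list and 0 of 6 others named by the size rule. The label gives no intestinal tissue and no biological explanation was tested.

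Of 6568 genes with at least 10 TPM in all 7 primary B libraries, 30 were under 0.1 TPM in CH12, among them Mtap, Satb1, a chromatin organiser, and Lrrk2, a kinase gene. Deleted stretches of the CH12 genome could cause this and cannot be told apart from silencing, as neighbouring pairs among the absent genes numbered 1, and 11.13% of 10000 random sets held as many. Mtap lies on chromosome 4 at 89137122 to 89181081 (GRCm38), and its neighbours Cdkn2a and Cdkn2b, cell cycle inhibitors, were listed at 0 in CH12 against 0.29 to 39.53 and 0.16 to 2.78 TPM in primary B libraries, while Klhl9, which ends at 88722465, was at 24.5 TPM in CH12. A quantification setting behind the length offset that CH12 shares with 3 other libraries could not be tested with these genes. They were chosen at 10 TPM or more in all 7 primary B libraries, of which LPS+IL4 B and splenic B share that offset. Genes lost to such a setting were thus left out beforehand. That 0.0% of 27 of these genes were absent from the ConA library therefore decides nothing. Genomic DNA was not analysed here.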
